A study of Crocodylus porosus with 60 samples.

How the data were processed

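Small RNA from tissues of hatchling saltwater crocodiles (Crocodylus porosus) was sequenced, and 60 deposited samples carry 15 library names, with 4 samples for each name. Per the labels, total RNA came from flash-frozen tissue and the libraries were built with a small RNA kit for Illumina sequencing. The deposited table has 654 rows, each listed as a mature miRNA, and 1 value column for each library name. The 4 samples of a name could therefore not be compared with each other. A further 1 value column matched no sample and was not used. The 15 libraries are 4 of testis, 2 of heart, 2 of brain and 1 each of jaw skin, tongue, cloaca, small intestine, stomach, liver and spleen. The value column used for cloaca is headed cloacal gland, while the sample titles say cloaca, so its levels may be those of the gland. The column headers name both runts and normal hatchlings for testis, heart and brain, so a runt and a normal library came from different animals. Nothing says that libraries of the same size class came from separate animals. The p-values measure only the spread between these libraries. In the tissue comparisons it holds size class, age and animal, and within a size class it may be technical. Of the rows, 145 carry the name of a known miRNA family and 509 carry an N with a number, which is how the table names miRNAs outside those families. Whether the N-numbered rows are true miRNAs was not checked here.

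The deposited values are RPM (reads scaled to a common library total), as read from the values themselves. The table's first line names the quantifier of miRDeep2 (version 2_0_0_8), per the file headers. The submitters' processing notes list Bowtie 1.2.0, bcl2fastq 2 and bedtools 2.26.0 without a role. The genome build is not given in the sources used here, and sequences and positions of the miRNAs were not analysed here. The total by which reads were divided is not stated. The listed rows sum to between 55.3% and 81.5% of the RPM total of a library. The smallest step between low values gave the worth of 1 read, and from it a depth of 540000 to 4760000 reads per library. Between 88.4% and 95.3% of the low values were whole multiples of that step within 0.1 reads, and others were fractions, as when a read that maps to several miRNAs is split. The values were therefore not treated as counts. Intervals on single-library levels are exact 95% Poisson intervals on the reads estimated from that step. Shares of reads have exact 95% binomial (Clopper-Pearson) intervals. Both cover counting error only, and a value of 0 allows up to 3 reads.

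The plan fixed before the data were examined assumed counts and a count model. Since the values are RPM, limma 3.58.1 in R 4.3.3 was used instead, on log2(scaled RPM + 1), with an intensity trend in the moderated variance. Scaling factors were a trimmed mean of log ratios without weights, trimming 30% of log ratios and 5% of mean levels. Rows with at least 10 RPM in at least 2 libraries were tested. The tissue model held all 15 libraries with tissue as its only term, and tissues with 1 library add nothing to the spread. P-values are two-sided and were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(RPM + 1) scale, which understates the change of low rows. Runts and normal hatchlings are told apart only by the column headers, so those comparisons were added after the table was seen. They were fitted with limma over the 8 testis, heart and brain libraries with tissue as a term, over the 4 testis libraries alone, and as the difference between the runt effect in testis and the mean of those in heart and brain, where only the 4 testis libraries give a spread. The limma steps were tested on simulated values with the spread of the real rows and 200 changed rows. In testis against heart, 56.2% of rows changed 4-fold and 96% of those changed 8-fold were recovered among 335 tested rows. For runts against normal hatchlings in testis, 37.5% at 4-fold and 90.9% at 16-fold were recovered among 247 tested rows.

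Levels over tissues used the mean RPM of each tissue, and rows that repeat a mature name were used once. Single-library tissues were compared with the mean of the other tissues without a test. In total 20 lists of miRNAs were fixed before the data were examined, for brain and neuron, striated muscle and heart, liver, smooth muscle and mesenchyme, gut epithelium, epithelium and skin, red blood cell, white blood cell, endothelium, gonad and germ line, ciliated cell, HOX cluster, pluripotent and early embryo, let-7, miR-17-92 and paralogous clusters, miR-30, miR-29, miR-181, miR-15/16, and miR-23/27/24. Members were matched by name, and lists can share members. Each list's total was set against 10000 random lists of the same size. In single-library tissues, the median log2 fold of each list with at least 3 rows was set against 10000 random lists matched on mean level, for 14 lists in 7 tissues. Similarity within known clusters was tested with 100000 permutations of locus names. On simulated levels of 140 loci, that test called 5 of 100 sets without an effect and 100 of 100 with like levels in 18 pairs. Rows named in the text follow a rule fixed before the data were examined. It takes the 25 most abundant rows, the 4 most abundant members of each list and any other member past a test, the 10 largest rises and 10 largest falls of each contrast among rows past the threshold with a mean of at least 10 RPM over the 2 groups and the same direction in every library (each library on its side of the other group's mean, and for testis against the other tissues each testis library against their mean), the 5 largest folds in each single-library tissue among rows with at least 100 RPM, every cluster with at least 2 members, the loci with both arms listed and the 5 most abundant N-numbered rows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

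Alternatives included median-ratio scaling, deposited RPM without scaling, no filter, other pseudocounts, a fit of testis, heart and brain alone, removal of the most abundant row, 1 row per mature name and leaving out each library in turn. The filter was applied again in each setting that used it, so a row could leave the test when a library was left out. Some rows share reads. The values of miR-211 were 0.5 times those of miR-204, those of miR-133c-5p were 0.5 times those of miR-133-5p, and 2 rows of miR-9-5p and several let-7 rows were proportional in the same way, so such rows are not separate measurements.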

Results

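Small RNA was profiled in 10 tissues of hatchling saltwater crocodiles to catalogue miRNAs and their expression over tissues. The labels also describe runts and normal hatchlings raised alike, with runts of 386.2 ± 23.6 mm (SD) at 359 days and normal hatchlings of 740.2 ± 73.5 mm at 373 days. Testis had 4 libraries, heart and brain 2 each, and jaw skin, tongue, cloaca, small intestine, stomach, liver and spleen 1 each. Estimated depth ran from 540000 reads in jaw skin to 4760000 in the brain library of a normal hatchling. Over the 319 rows with at least 10 RPM in 2 libraries, log2 levels of libraries of the same tissue correlated at r of 0.93 to 0.98 in 8 pairs, and libraries of different tissues at 0.57 to 0.95 in 97 pairs. These are correlations across miRNAs, which are not independent replicates.

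A few miRNAs made up most of the listed reads. The 10 most abundant rows took 64.9% of the listed total when each tissue counted once, and the first 25 took 85.9%. The most abundant row was miR-N444, which carries no family name, with 123000 ± 97570 RPM (SD over 10 tissues). It ranged from 2.01% of all RPM in spleen to 60.01% in a testis library of a normal hatchling. Over all estimated reads its share was 17.68% (exact binomial 95% interval 17.67 to 17.7%). It was followed by miR-148-5p (55710 ± 45590 RPM), miR-26a-5p (47880 ± 23580 RPM), miR-30a-5p (47190 ± 27200 RPM) and miR-N1 (32500 ± 51860 RPM). Broadly distributed rows among the 25 included miR-181a-5p, miR-425-5p, miR-92-1-5p, miR-125b-5p, miR-191, miR-30c-5p and 5 rows of let-7, the family whose rise accompanies differentiation in animals. Other rows of the 25 owed their rank to few tissues, among them miR-122-5p, miR-205a, miR-215-5p, miR-145, miR-204, miR-200a-5p, miR-150, miR-21-5p and miR-133-5p. The 5 most abundant N-numbered rows were miR-N444, miR-N1, miR-N449 (3232 RPM), miR-N288 (1347 RPM) and miR-N440 (1193 RPM). N-numbered rows took 25.1% of the listed total, and 8.1% once miR-N444 was left out.

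Many of the fixed lists were highest in the tissue they are known from, but not all. Brain and neuron rows summed to 67190 ± 8197 RPM in brain (SD, n = 2) and to 630.6 RPM in liver. Striated muscle and heart rows summed to 63290 ± 1655 RPM in heart (n = 2), 15380 RPM in tongue and 77.7 RPM in liver. Smooth muscle and mesenchyme rows reached 110500 RPM in stomach and 3240 ± 545.7 RPM in brain. Gut epithelium rows reached 81510 RPM in small intestine, epithelium and skin rows 149900 RPM in jaw skin, and white blood cell rows 78030 RPM in spleen. The 2 red blood cell rows were also highest in spleen (900.8 RPM), as were miR-126-5p of endothelium (10510 RPM) and the miR-15/16 family (15760 RPM). Gonad and germ line rows summed to 801.4 ± 276.2 RPM in testis (n = 4) and 800.7 ± 483.8 RPM in brain, so their sum did not set testis apart from brain. Of these 4 rows 3 are also the ciliated cell rows, which summed to 548.6 ± 355.8 and 800.6 ± 484 RPM. The remaining row, miR-202-5p, had 252.8 ± 159.9 RPM in testis and 0.105 ± 0.1485 RPM in brain. HOX cluster rows summed to 4812 ± 1092 RPM in testis (n = 4) and 9.8 ± 10.5 RPM in brain. The miR-30 family was highest in heart (121800 ± 66370 RPM) and miR-181a-5p in brain (84540 ± 60340 RPM). The let-7 family took 7.35% of the listed total and stayed between 26180 RPM in small intestine and 75900 RPM in cloaca. The miR-17-92 group and its member miR-92-1-5p, the only matched member of the early embryo list, peaked in cloaca at 44530 and 42200 RPM. The miR-23/27/24 clusters peaked in jaw skin (13310 RPM), and miR-29b-1-5p stayed at or under 18.2 RPM in every tissue. Of the 20 lists, 7 exceeded the 95th percentile of random lists of their size. They were liver, smooth muscle and mesenchyme, endothelium, early embryo, let-7, miR-30 and miR-181. The random lists were drawn from all rows, most of them N-numbered and low, so lists of family-named rows tend to rank high. The liver, endothelium, early embryo and miR-181 lists matched 1 row each, so their percentile is the rank of that row.

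**Figure D1:**
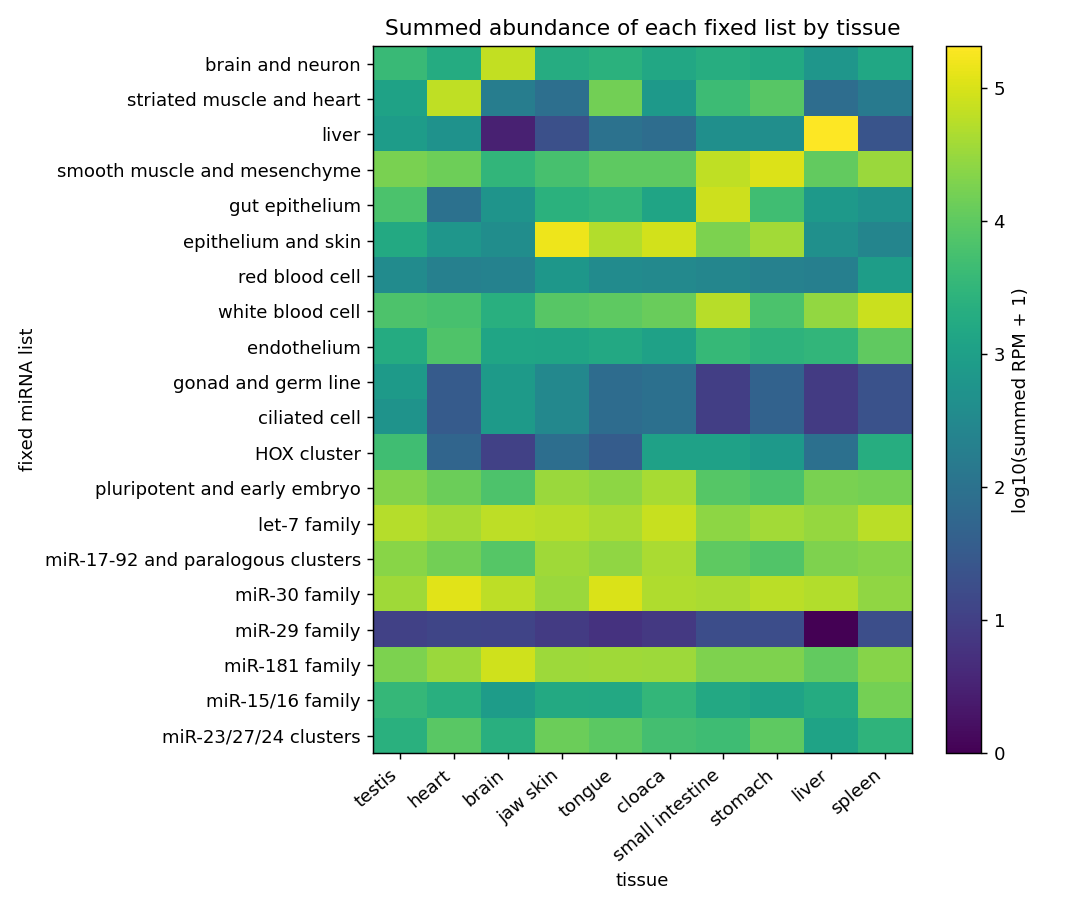
Summed abundance of the 20 fixed lists (rows) in 10 tissues (columns), as log10(summed RPM + 1) on the colour scale, with means over libraries for testis, heart and brain. The brightest cell is the liver list in liver, where miR-122-5p had 208200 RPM.

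Testis against heart asked which miRNAs set the gonad apart from a striated muscle organ. Testis had high levels of rows that were almost missing from heart. The largest rise in testis was that of miR-N341, with 2462 ± 778 RPM in testis (SD, n = 4) and 0.575 ± 0.813 RPM in heart (n = 2; log2 fold 10.57, SE 0.58, adjusted p = 2.54e-07). Next came miR-10c-5p, which lies in a HOX cluster in other vertebrates, at 4314 ± 910 RPM against 13.2 ± 15.5 RPM. miR-202-5p, known for its expression in vertebrate gonads, had 252.8 ± 159.9 RPM in testis and was listed at 0 in both heart libraries. miR-34b-5p, a miRNA of germ cells and multiciliated cells, had 451.4 ± 381 RPM against 1.2 ± 1.69 RPM. Heart was higher in miR-499-3p, whose gene lies in a cardiac myosin gene in other vertebrates, with 10800 ± 6336 RPM against 22.5 ± 38.5 RPM (log2 fold -10.70, SE 1.33, adjusted p = 4.815e-05).

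Of 319 rows tested, 74 were higher in testis and 34 lower. Of the 129 rows with a family name, 12 were higher and 18 lower, and of the 190 N-numbered rows, 62 were higher and 16 lower. Further large rises were miR-N458 (596.5 ± 209 RPM), miR-N426 (294.8 ± 169.8 RPM), miR-N310, miR-N21, miR-N419 and miR-N19. Of 7 striated muscle and heart rows, 6 were lower in testis, and 6 also when adjusted over the list alone, where the skeletal muscle row miR-206 was higher in testis. They included miR-133-5p (32560 ± 7574 RPM in heart, 655.8 ± 927.3 RPM in testis), miR-1-1-5p, miR-1b-5p and miR-133-3p. One testis library from a runt held most of this muscle signal, with 2021 RPM of miR-133-5p. miR-490-5p, miR-N46, miR-N29 and miR-N99 were lower in testis too. All 3 HOX cluster rows (miR-10c-5p, miR-10a-5p and miR-196) were higher, and 3 when adjusted over the list alone. Of 4 gonad and germ line rows 2 were higher, and 2 of 4 gut epithelium rows, miR-375 and miR-31. Of 4 miR-30 rows, miR-30a-5p and miR-30e-5p were lower, and of 4 miR-23/27/24 rows, miR-27-5p, miR-24-3p and miR-23-3p were lower. miR-144-5p of the red blood cell list and miR-383-5p of the brain list were lower, and let-7g-5p was the 1 of 9 let-7 rows that was higher, but miR-383-5p and let-7g-5p did not pass when adjusted over the list alone. No row of the liver, smooth muscle, epithelium, white blood cell, endothelium, early embryo, miR-17-92, miR-29, miR-181 or miR-15/16 lists passed.

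Testis against brain gave the same kind of contrast with neural tissue. Brain was higher in miR-9-5p, a miRNA of neural progenitors and neurons, with 24520 ± 15940 RPM (n = 2) against 112 ± 38 RPM in testis (log2 fold -7.82, SE 0.74, adjusted p = 6.683e-06). miR-124-5p, from a neuronal miRNA gene, had 89.2 ± 24.9 RPM against 1.33 ± 1.53 RPM. Testis was higher in miR-N341 (log2 fold 10.97, SE 0.58), miR-10c-5p, miR-N458, miR-N426, miR-N310, miR-N419, miR-202-5p, miR-N21, miR-N463 and miR-N319. miR-N458, miR-N426, miR-N310, miR-N21, miR-N463 and miR-N319 were listed at 0 in both brain libraries.

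Of 319 rows, 86 were higher in testis and 58 lower, with 22 and 28 among rows with a family name. Of 9 brain and neuron rows, 8 were lower in testis, and 8 when adjusted over the list alone. They were miR-128-1-5p (22390 ± 8759 RPM in brain), miR-9-5p, miR-129-5p, miR-132, miR-138-5p, miR-383-5p, miR-124-5p and miR-137-5p. miR-490-5p, miR-N312 (1016 ± 1103 RPM), miR-N542, miR-N41, miR-N363 and miR-N22 were also higher in brain. In the opposite direction stood all 3 HOX cluster rows and all 3 smooth muscle and mesenchyme rows, miR-145, miR-199-5p and miR-214-5p. miR-150 and miR-223 of 5 white blood cell rows, miR-215-5p, miR-194 and miR-375 of 4 gut epithelium rows, and miR-122-5p were higher in testis. So were miR-16c and miR-15c-5p of 7 miR-15/16 rows and miR-23a of 4 miR-23/27/24 rows. Each of these counts was equal when adjusted over the list alone, whereas single rises of miR-200b-5p, miR-30c-5p and, in the miR-17-92 list, miR-92-1-5p were not kept. In the gonad and ciliated cell lists, miR-449a-5p and miR-449b-5p were lower in testis, while miR-34b-5p did not differ past the threshold (451.4 ± 381 RPM against 428.1 ± 281.8 RPM). miR-181a-5p and miR-144-5p were lower. No striated muscle, endothelium, let-7 or miR-29 row passed. Without the brain library of the runt, fewer rows were lower in testis, and the log2 fold of miR-N22 was -3.93 instead of -5.53. Rows high in brain alone then missed the filter and were no longer tested, so the lower count is in part by construction. Some of the named rows were among them.

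Heart against brain set a muscle organ against neural tissue, and known muscle and neural miRNAs were among the rows that differed. Heart was higher in miR-499-3p (log2 fold 11.06, SE 1.53, adjusted p = 4.097e-04) and miR-133-5p (32560 ± 7574 RPM against 99.9 ± 8.15 RPM, n = 2 each). Brain was higher in miR-34b-5p (428.1 ± 281.8 RPM against 1.2 ± 1.69 RPM), miR-9-5p and miR-132 (6758 ± 7135 RPM against 95.6 ± 91.3 RPM). Of 319 rows, 24 were higher in heart and 47 lower. Of 7 striated muscle and heart rows 6 were higher in heart, and of 9 brain and neuron rows 8 were lower, with 6 and 8 when adjusted over the lists alone. miR-133-3p, miR-1-1-5p, miR-1b-5p, miR-N46, miR-N20 (348.7 ± 36.7 RPM) and miR-23a were among the largest rises in heart. miR-122-5p, the main liver miRNA of vertebrates, was also higher in heart (516.1 ± 570.6 RPM against 2.1 ± 0.29 RPM), with a call that ended without the heart library (adjusted p = 0.06079) or the brain library (0.09289) of the runt. The call of miR-23a ended in these 2 settings too (0.06505 and 0.07583), that of miR-1-1-5p without the brain library of the runt (0.05318), and that of miR-338-3p without this library (0.05682) or the heart library of the normal hatchling (0.05608). miR-338-3p, miR-124-5p, miR-N542, miR-N22, miR-N41 and miR-N312 were among the largest falls. All 3 ciliated cell rows, miR-34b-5p, miR-449a-5p and miR-449b-5p, were lower in heart. miR-199-5p, miR-214-5p, miR-10a-5p, miR-30c-5p and miR-23-3p were higher, and miR-31, miR-205a, miR-203-5p and let-7i lower. Over the lists alone the counts were equal except for 3 lower epithelium and skin rows instead of 2, 3 higher miR-23/27/24 rows instead of 2, 0 lower let-7 rows instead of 1, and 1 row each for endothelium (higher) and miR-181 (lower). The counts rest on 2 libraries each and moved when a heart or brain library was left out. In each of these settings some of the named rows missed the filter and were no longer tested, so lower counts are in part by construction.

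Testis against the mean of the other tissues asked which miRNAs mark testis among the 10 tissues. miR-N341 again led (2462 ± 778 RPM, n = 4, against 0.806 ± 1.82 RPM over 9 tissues; log2 fold 10.64, SE 0.39, adjusted p = 3.263e-09). miR-202-5p was at 252.8 ± 159.9 RPM against 0.0528 ± 0.124 RPM (log2 fold 7.63, SE 0.58). The skin and epithelial rows miR-205a (29.4 ± 14.4 RPM against 24100 ± 42810 RPM) and miR-203-5p were lower in testis than this mean, which hides a wide range. miR-205a was at 116100 RPM in jaw skin but at 4.84 RPM in spleen, under its level in each testis library, and miR-203-5p was at 0.63 RPM in stomach. In all, 86 of 319 rows were higher and 25 lower. N-numbered rows made up 71 of the 86, against 15 with a family name. miR-N458, miR-N426, miR-N310, miR-N419, miR-N21, miR-N19, miR-N463 and miR-N319 were the other large rises.

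All 3 HOX cluster rows were higher in testis, and 3 when adjusted over the list alone. miR-202-5p and miR-34b-5p of 4 gonad rows, miR-34b-5p as the 1 of 3 ciliated cell rows, and miR-375 of 4 gut epithelium rows were higher. So were miR-129-5p and miR-138-5p of 9 brain rows, and all these counts were equal over the lists alone. The mean of the other tissues is taken on log2 levels, and it hides brain. Both brain rows were lower in testis than in brain (miR-129-5p 1929 ± 2241 against 11270 ± 7189 RPM). Among the HOX cluster rows, miR-10a-5p had 308.3 RPM in testis but 586.8 RPM in spleen and 507.5 RPM in stomach. miR-196 had 189.8 RPM in testis and 519.8 RPM in cloaca, so of these rows only miR-10c-5p was highest in testis. Of 6 epithelium and skin rows 4 were lower (miR-205a, miR-203-5p, miR-200a-5p and miR-429-3p), and 4 over the list alone. The level of miR-375 in testis was set by the 2 libraries of runts (10570 and 12140 RPM). Those of normal hatchlings had 234 and 128.4 RPM, less than small intestine (3467 RPM), tongue (2954 RPM) or stomach (2179 RPM), though more than any heart (9.19 and 23.24 RPM) or brain library (61.39 and 36.99 RPM). miR-27-5p and miR-23-3p of the miR-23/27/24 clusters (3 rows over the list alone) and miR-144-5p (1 over the list alone) were lower. miR-18b was higher and miR-1b-5p lower, without passing over their lists alone. miR-N521, miR-1662, miR-N17 and miR-N353 completed the largest falls. No row of the other fixed lists passed. Without scaling 13 rows were lower instead of 25, and 13 or 14 without either testis library of a normal hatchling or the second of the runts. With heart and brain as the only other tissues, miR-203-5p, miR-N17, miR-429-3p and miR-200a-5p turned to the other direction without passing the threshold, and miR-205a no longer differed (log2 fold -0.21, adjusted p = 0.795). The calls of miR-429-3p, miR-200a-5p, miR-1b-5p and miR-N353 were each lost in 2 or more of the other settings.

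**Figure D2:**
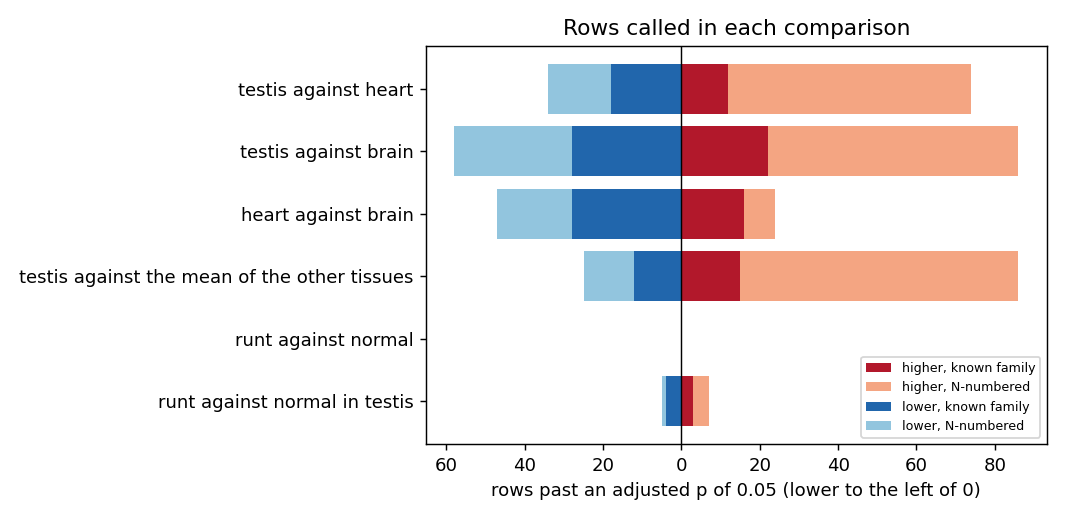
Number of rows past an adjusted p of 0.05 in each comparison, with higher rows to the right of 0 and lower rows to the left, split into rows with a family name and N-numbered rows. Of the 86 rows higher in testis than in the mean of the other tissues, 71 were N-numbered.

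Single-library tissues had no replicates, so their differences have no replicate check and no test. Liver stood out by miR-122-5p, at 208200 RPM (95% Poisson interval 207100 to 209200) against a mean of 276.6 RPM in the other tissues, a fold of 753. miR-N336 followed at 180.8 RPM, at least 71.7-fold higher, then miR-N67, miR-N288 and miR-148-5p. In small intestine, miR-215-5p (59670 RPM, fold 299) and miR-194 (13800 RPM, fold 62.9), both miRNAs of gut epithelium, were followed by miR-216a (295.3 RPM, fold 55.3), miR-31 and miR-N1. miR-216a is known from the pancreas. Stomach shared miR-N1 with small intestine (134000 and 125400 RPM), and led in miR-187-5p (28100 RPM, fold 18.7), miR-1416, miR-145 of smooth muscle (107500 RPM, fold 7.19) and miR-200a-5p.

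Jaw skin and cloaca shared the epithelial miR-205a, at 116100 and 76170 RPM. Jaw skin also led in miR-203-5p (16180 RPM, fold 24.9), miR-204 (55600 RPM, fold 16.1) with its read-sharing row miR-211, and miR-193a-3p. In cloaca the largest folds against the mean of the other tissues were those of miR-196, a HOX cluster miRNA (519.8 RPM, fold 24.1), miR-N17, miR-205a, miR-155-5p, which was higher in spleen (2706 against 1686 RPM), and miR-N315. In tongue they were those of the skeletal muscle miRNA miR-206 (248.1 RPM, interval 214.6 to 285.4, fold 31.1) and miR-183, a miRNA of sensory cells (618.9 RPM, fold 15.8), then miR-429-3p, miR-N558 and miR-375. The last 3 had higher levels elsewhere, miR-429-3p in stomach (2130 against 1886 RPM), and miR-N558 (201.2 against 151.9 RPM) and miR-375 (5768 against 2954 RPM) in testis. Spleen led in the erythroid miR-144-5p (230.3 RPM, fold 25.1), the myeloid miR-223 (1302 RPM, fold 11.6), the lymphoid miR-150 (36220 RPM, fold 10.4), miR-16c (14260 RPM, fold 10.1) and miR-184-5p. It also had the most rows at least 4-fold above the mean of the other tissues, 15 of the 87 at 100 RPM or more, against 8 in small intestine, 6 in stomach, 5 in jaw skin, 4 in cloaca, 4 in liver and 2 in tongue. Against the median of the other tissues these counts were 23, 19, 16, 12, 14, 9 and 15.

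Among the 98 pairs of a list and a single-library tissue, the white blood cell list in spleen (median log2 fold 3.15, percentile 99.9 of matched random lists), the miR-15/16 family in spleen (1.95, percentile 99.8), the gut epithelium list in small intestine (4.47, percentile 99.9), the epithelium list in tongue (1.15, percentile 100) and jaw skin (0.81, percentile 97.2), and the striated muscle list in tongue (0.89, percentile 99.7) stood high. So did the ciliated cell list in jaw skin (1.43, percentile 99.7), the miR-17-92 group in spleen (1.39, percentile 98.8), the white blood cell list in liver (0.56, percentile 98.5), let-7 in cloaca (0.5, percentile 96.7), the miR-23/27/24 clusters in stomach (0.91, percentile 96.3) and jaw skin (1.31, percentile 96.2), and the miR-30 family in liver (0.06, percentile 95.1). The striated muscle list was lowest in liver (-6.43, percentile 0) and the brain list lay at or under percentile 0.3 in all 7 tissues. The mean of the other tissues holds heart and brain, where these lists were highest. Low values elsewhere thus follow largely from this reference and say little about the 7 tissues themselves.

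Runts and normal hatchlings were compared because the column headers tell them apart in testis, heart and brain. In testis, miR-375, known from pancreatic islets and other endocrine cells, was higher in runts, at 11360 ± 1115 RPM (SD, n = 2) against 181.2 ± 74.7 RPM (n = 2; log2 fold 5.43, SE 0.24, adjusted p = 2.481e-04). Its call held in every alternative, with log2 folds of 5.22 to 6.02. The settings without a heart or brain library cannot change this fit and are no check on it. miR-202-5p was lower in runts, at 118.7 ± 12.1 RPM against 386.9 ± 67.9 RPM (log2 fold -2.28, SE 0.37, adjusted p = 0.04439), but this call was lost in 7 settings. They were median-ratio scaling (adjusted p = 0.05364), deposited RPM (0.1769), no filter (0.09354), removal of the most abundant row (0.06284), and the fits without either testis library of a normal hatchling (0.1449 and 0.3612) or the second of the runts (0.05271). miR-204 was lower too, at 3566 ± 722.9 RPM against 11270 ± 5577 RPM, with miR-211 sharing its reads, and its call was lost with deposited RPM (log2 fold -1.58, adjusted p = 0.05095) and without either testis library of a normal hatchling (0.05412 and 0.1365).

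Over the 4 testis libraries 7 of 234 rows were higher in runts and 5 lower. The others with a mean of at least 10 RPM over the 2 groups were miR-139-5p, miR-N523, miR-N434, miR-218-5p and miR-N440 (2625 ± 267.8 RPM against 628.1 ± 243.3 RPM), which were higher, and miR-N540 and miR-22-3p, which were lower. Under that mean, miR-N22 had the second largest rise of the called rows, from 0.255 ± 0.361 to 15.9 ± 0.962 RPM (log2 fold 3.35, SE 0.47, adjusted p = 0.02979), and its call was not followed through the alternatives. From the fixed lists, 1 of 6 brain rows (miR-218-5p) and 1 of 4 gut epithelium rows (miR-375) rose and 1 of 4 gonad rows (miR-202-5p) fell. Adjusted over each list alone, 3 brain, 2 striated muscle, 3 epithelium and skin, 1 gut epithelium, 1 liver, 1 HOX cluster, 1 early embryo and 1 miR-23/27/24 row were higher, and 3 white blood cell rows, 1 gonad row and 1 row each of the red blood cell, endothelium, let-7 and miR-15/16 lists were lower. The 2 striated muscle rows, miR-133-5p and miR-133c-5p, share reads and are 1 measurement. In testis libraries 1 and 2 of the runts miR-133-5p had 2021 and 449.9 RPM. The liver row miR-122-5p had 285.9 and 3152 RPM there, so 1 library sets much of each rise. These calls depended on the setting. Of the 11 named rows, 8 lost the call under median-ratio scaling, 8 without a filter, 8 without the most abundant row and 6 with deposited RPM. Without either testis library of a normal hatchling, 9 of the 10 still tested lost it. Deposited RPM gave 24 higher and 0 lower rows (100% higher instead of 58.3%), and the median log2 difference of all rows was 0.56 above that after scaling. Leaving out 1 testis library gave 2 to 16 higher and 0 to 11 lower rows. The 2 testis libraries of runts were also the shallower ones, at 1120000 and 1140000 reads against 1660000 and 1960000.

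Over testis, heart and brain together, limma called 0 of 293 rows between runts and normal hatchlings, with 22 at an unadjusted p under 0.05, of which miR-N22 had the smallest (log2 fold 2.45, adjusted p = 0.2842). Size class was known from the column headers alone, and exchanging the 2 heart libraries gave 39 rows. Adjusted over the lists alone, 2 of 9 brain rows and miR-122-5p were higher in runts. Deposited RPM gave 1 higher row, and 6 were higher and 3 lower without either heart library. The runt effect differed between testis and the mean of heart and brain for 3 rows, miR-375 (log2 difference 5.15, SE 0.32), miR-204 (-3.86, SE 0.24) and miR-211 (-3.85, SE 0.24), each at an adjusted p of 0.01644. Heart and brain had 1 library of each size class, so the spread came from the 4 testis libraries alone and the runt effects in heart and brain have no replicate check. None passed when any 1 of the 4 testis libraries was left out or without scaling.

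**Figure D3:**
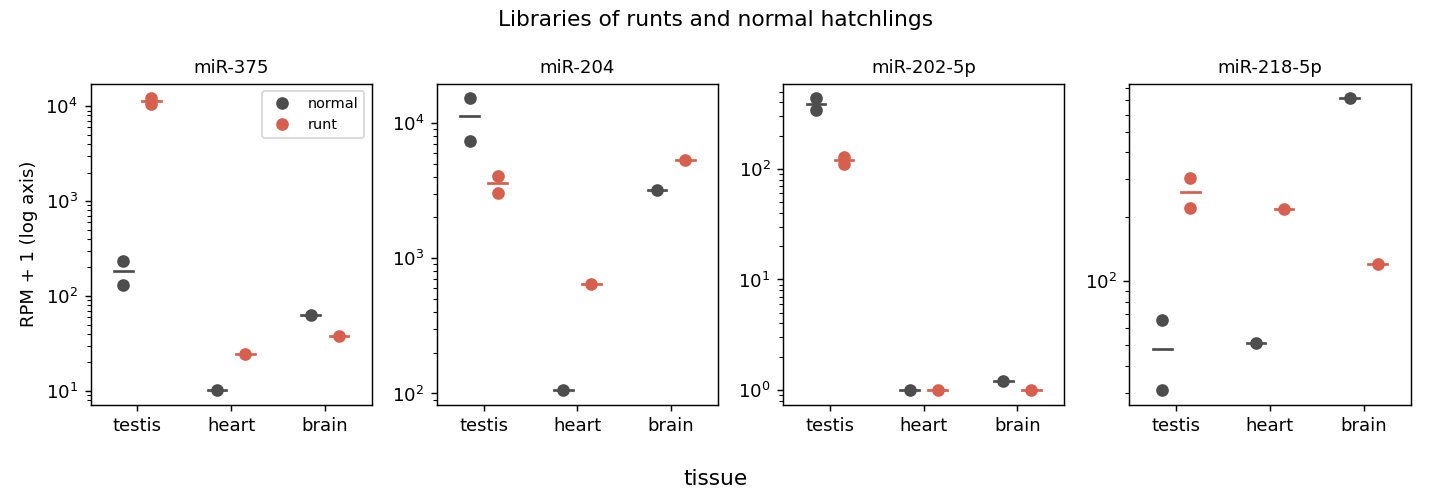
Levels of 4 miRNAs as RPM + 1 on log axes in testis, heart and brain libraries of normal hatchlings (grey) and runts (red), with points for libraries and short lines for means. miR-375 in testis was 10570 and 12140 RPM in runts and 128.4 and 234 RPM in normal hatchlings.

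Members of known clusters, which are processed from a shared primary transcript, had closer levels than random pairs. The mean absolute log10 difference was 0.8 over 18 pairs in 14 clusters, against 1.45 ± 0.258 (SD) for random pairs of the 138 loci (permutation test, two-sided, p = 0.00638). Loci are not independent replicates. miR-221-5p and miR-222a differed by a ratio of 1.11, let-7f-5p and let-7a-5p by 1.4, miR-130c-5p and miR-301b-5p by 1.69, miR-199-5p and miR-214-5p by 1.9, miR-191 and miR-425-5p by 2.67, miR-449a-5p and miR-449b-5p by 3.62, and miR-215-5p and miR-194 by 3.9. Wider ratios were found for miR-30a-5p and miR-30c-5p (4.99), the miR-200b, miR-200a and miR-429 cluster (7.4), miR-100-5p and miR-125b-5p (14.8), miR-17a-5p, miR-19b-5p and miR-20a-5p (19.4), miR-183 and miR-96 (52.5), and miR-16c with miR-15b-5p (108) or miR-15a (156). miR-16c stood in for miR-16 in both clusters, as the most abundant row of that name. Whether it is the partner in either was not checked, so the ratios of 108 and 156 may not be those of true cluster members. Without clusters whose members share a seed family the difference was 0.735 (p = 0.0713). Both arms were listed for only 2 loci. miR-133 had 98.5% of its reads on the row named 5p (exact binomial 95% interval 98.4 to 98.5%), and miR-153 had 28 reads in all, under the minimum of 100. The arm names are those of the table and could not be checked against sequences.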

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

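The tests in this part were chosen after the results were seen, except those of read depth and of the number of libraries for the N-numbered rows. The 4 testis libraries were checked for a value far from the other 3 in 102 quantities, and 10 were found where chance gives about 5.1. Of these, 2 were single reads and count for nothing: miR-N363 at 0.87 RPM in testis library 2 of the runts and miR-N46 at 0.6 RPM in testis library 1 of the normal hatchlings. The other 8 follow. In testis library 1 of the runts, miR-499-3p had 79.77 RPM (0 to 9.63 in the others) and miR-1-1-5p 218.2 RPM (17.6 to 20.1). In testis library 2 of the runts, miR-122-5p had 3152 RPM (43.3 to 285.9), miR-490-5p 74.28 RPM (3.57 to 15.2) and miR-N312 9.61 RPM. In testis library 1 of the normal hatchlings, miR-N21 had 915.6 RPM (51.5 to 157.2). In testis library 2 of the normal hatchlings, miR-205a was low at 8.15 RPM (35 to 39.7) and miR-150 at 2189 RPM (3785 to 4106).

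The runt effect in testis differed from the mean of those in heart and brain for miR-375 (log2 difference 5.15), miR-204 (-3.86) and miR-211 (-3.85), by limma at an adjusted p of 0.01644 each. With 1 library per size class, the effects in heart and brain have no replicate spread, and that of the 4 testis libraries stands in for it. miR-375 in runt testes was at least 10570 RPM, against at most 234 RPM in normal testes. Scaling and the share of miR-N444 cannot account for this gap, since per total without miR-N444 the lower runt library was still 41.7-fold above the higher normal library. No library of the 9 other tissues analysed here reached this level. The lower runt testis was 3.05-fold above small intestine, the highest library of another tissue at 3467 RPM. Small intestine, tongue and stomach are 1 library each without a stated size class, so they do not bound miR-375 in those tissues of runts. RNA of those tissues in runts, RNA of a tissue not analysed here, size, age and the animals themselves stay open and untested.

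The raised muscle rows in testis library 1 of the runts are a second pattern. Heart RNA would have to make up 6.21% of that library to give its miR-133-5p, and its miR-206, at 157.8 RPM, was 737-fold above the most that this share allows. Tongue RNA would have to make up 21.2% and bring 5181 RPM of miR-205a, while 35 RPM were found, 0.00675 of that level. miR-200a-5p stood at 0.548 of the level from tongue, which testis itself can supply. Skeletal muscle RNA was not tested and stays open as a hypothesis.

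N-numbered rows restricted to testis are the third pattern. In all, 30 such rows had at least 10 RPM in each testis library and no more than 3 reads in any other library, and 3 rows met the same terms for brain (exact binomial test, two-sided, p = 1.4e-06). Brain had more estimated reads, so read depth does not account for the difference. Per library, testis had 5 times as many restricted rows as brain. How such rows grow with the number of libraries is not known, so this ratio cannot exclude that number as a cause. Whether these rows are true miRNAs, and whether they were predicted from all libraries alike, was not tested. A biological difference between testis and the other tissues remains a hypothesis.

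For testis against the mean of the other tissues, 1 of 100 splits of the libraries, the real one, called as many as the real 111 rows. The highest other split called 72, and the median of the other splits was 0. Those splits mix tissues within a group, which widens the spread and lowers their counts, so they cannot exclude chance. For runts against normal hatchlings over 3 tissues, where 0 rows were called, 34 of 34 splits called as many, as any split must, so their count says nothing about chance. The highest other split called 39 rows, which points to a structure of the libraries, but it is the largest of splits that otherwise called 0 to 3, and no test set it against chance. It set the heart library of the runt with the libraries of normal hatchlings in testis and brain, and these are the deeper libraries of each tissue. Size class is known from the column headers alone, and exchanged headers of the 2 heart libraries would give this same split. The most abundant row, miR-N444, ran as the headers say, lower in the runt in heart (4.55 against 12.74% of RPM), in brain (5.35 against 23.01%) and in both testis libraries (28.96 and 26.54 against 34.36 and 60.01%). That is 1 row, not called (log2 fold -1.84, adjusted p = 0.2842). Neither depth nor an exchange was tested, so both stay open, and the difference of the runt effect between testis and the mean of heart and brain rests on these headers too.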

How the results depend on the processing

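Alternatives for the runt comparisons, other pseudocounts and the mean over libraries for the lists were chosen after seeing the data. Of the log2 folds of named rows, 1070 kept direction and call under alternatives chosen before the data were examined, 24 lost the call and 4 changed direction. Under added ones 262 kept both and 61 lost the call. Named rows that were no longer tested in a setting are in none of these counts. All 61 losses were for runts in testis, whereas the 262 include the pseudocount settings of the tissue contrasts. Leaving out a heart or brain library cannot change the fit of the 4 testis libraries. Those settings kept every call by construction, that of miR-375 among them. The counts for testis against heart stayed within 1.5 times in every setting run. The 4 changes of direction came in the fit with testis, heart and brain alone, where miR-203-5p had a log2 fold of 0.26, miR-N17 0.94, miR-429-3p 1.14 and miR-200a-5p 1.57 against the mean of heart and brain, from which the epithelial tissues are missing by construction. That fit gave 50 lower rows. Deposited RPM without scaling gave 13 lower rows in testis against the mean of the other tissues, 1 higher row for runts over 3 tissues, 24 higher and 0 lower for runts in testis, and 0 in both directions for the difference of the runt effect. The median log2 difference of all rows then moved by 0.13 for testis against brain and by 0.52, 0.56 and 0.59 for the runt comparisons. Without a filter more rows are tested, and there were 102 lower rows in testis against brain, 130 higher in testis against the other tissues, 1 higher and 2 lower for runts in testis, and 5 higher and 14 lower for the difference of the runt effect. For runts in testis, median-ratio scaling gave 2 higher and 2 lower rows, removal of the most abundant row 1 and 2, 1 row per mature name 3 and 3, and a pseudocount of 5 gave 13 higher. The cause was not tested.

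Leaving out 1 library in turn gave 25 to 58 lower rows in testis against brain, 10 to 28 higher and 15 to 45 lower in heart against brain, and 13 to 36 lower in testis against the other tissues. For runts over 3 tissues it gave 0 to 6 higher and 0 to 3 lower rows, for runts in testis 2 to 16 and 0 to 11, and for the difference of the runt effect 0 in both directions without any testis library. That difference could not be fitted without a heart or brain library. A library left alone in its group is assumed to vary like the other groups. Rows high in that library alone miss the filter and are not tested, which lowers such counts by construction. miR-375 in runt testes kept its call, with adjusted p from 1.196e-16 to 0.02246 over the alternatives.

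In single-library tissues, the median of the other tissues instead of the mean gave 12 rows at least 4-fold higher in jaw skin, 15 in tongue, 14 in cloaca, 19 in small intestine, 16 in stomach, 9 in liver and 23 in spleen, and scaled RPM gave 2 in cloaca. A minimum of 10 reads left 2 loci with both arms. Without clusters of shared seed families, fewer pairs remained and the mean log10 difference was 0.735 (p = 0.0713). A second count model, each deposited sample as a replicate, and the agreement of the 4 samples of a library were not run, since the values are RPM in 1 column per library. No paired analysis was possible because the columns carry no replicate numbers shared between tissues. Depth limits rows near 10 RPM most in jaw skin, where 3 reads are worth 5.56 RPM.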

Other observations

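The test of cluster members was chosen before its result was seen, and that of N-numbered rows after. HOX cluster miRNAs were split by tissue. miR-10c-5p had 1499 RPM in spleen, 926 RPM in small intestine, 467.3 RPM in cloaca and 208.1 RPM in stomach, but 64.8 RPM in jaw skin and 11.4 RPM in tongue. miR-196 had 519.8 RPM in cloaca and 189.8 ± 222.8 RPM in testis (SD, n = 4), and at most 1.85 RPM in the other tissues. Its testis mean was set by the runts, at 345 ± 229.6 RPM against 34.7 ± 0.615 RPM in normal hatchlings (n = 2 each). The ciliated cell rows miR-449a-5p and miR-449b-5p had 247.2 and 52.8 RPM in jaw skin beside 280.4 ± 159.3 and 92.1 ± 42.8 RPM in brain (n = 2), while miR-34b-5p had 3.7 RPM in jaw skin and 428.1 ± 281.8 RPM in brain.

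One hypothesis was that members of a known cluster vary together over tissues because they share a primary transcript. The mean correlation over the 10 tissues was 0.691 for 18 within-cluster pairs and 0.0414 ± 0.091 (SD) for random pairs (permutation test, two-sided, p = 2e-05, the smallest that 100000 permutations can give). This is consistent with shared transcription, although pairs with near-identical sequence can also share reads. The miR-200b, miR-200a and miR-429 cluster had a mean r of 0.99, miR-449a-5p and miR-449b-5p 0.97, and miR-221-5p and miR-222a 0.94, while let-7a-5p and let-7f-5p had 0.02.

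A further hypothesis was that N-numbered rows are more often higher in testis than rows with a family name. Of the tested rows, 37.4% of N-numbered and 11.6% of family-named rows were higher in testis than in the mean of the other tissues (Fisher's exact test, two-sided, p = 1.93e-07, odds ratio 4.53). Rows were treated as independent, which rows that share reads are not. A row restricted to testis could pass the filter of 10 RPM in 2 libraries, whereas one restricted to a single-library tissue could not. Of the N-numbered rows 190 of 509 were tested, and of the family-named rows 129 of 145. The filter thus favours N-numbered rows that are high in testis and can raise the odds ratio.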
